A study of Mus musculus with 354 samples.

How the data were processed

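Liver RNA was measured on 354 one-colour Affymetrix HT_MG-430 PM arrays, 1 per male mouse, from 45 inbred strains of the Collaborative Cross, a mouse panel bred from several founder strains. There were 179 arrays from animals given vehicle and 175 from animals given tolvaptan, a blocker of the vasopressin V2 receptor, taken 24 h after treatment. Of the 90 combinations of strain and treatment, 85 held 4 animals, 4 held 3 and 1 held 2. Per the labels' protocols the animals were 8 to 10 weeks old, were acclimated for about 7 days and were fasted for about 18 h. The dose label gives no unit and is not used. Each array holds a separate animal, so the spread between arrays includes the spread between animals.

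The deposited values are on the log2 scale and, per the submitters' processing notes, came from RMA in the Affymetrix Expression Console. No versions are given in the sources used here, and whether all arrays were normalized together is not stated. The table held 42597 probe sets with values from 0.97 to 13.96. The median over the non-control probe sets lay between 2.81 and 3.02 per array, and the 75th percentile between 4.55 and 5.36. Arrays have no read depth, and the number of arrays limits the precision. The annotation gave 1 gene symbol for 27691 probe sets, several for 493 and none for 14376, besides 37 control probe sets. The Entrez identifiers of 27494 of the first kind were found in the RefSeq gene table of assembly GRCm38.p6, which was used only for names. Gene positions are not given, because no genome build is named for these values.

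Each gene was represented by its single-symbol probe set with the highest mean over all arrays, and was kept when it lay above the array's median in at least 4 arrays. This left 14125 genes. The model, fitted with limma 3.58.1 in R 4.3.3, had 1 mean for each strain and treatment plus scan date, coded as 6 scans with scan 1 the earliest. Scan 1 held 1 animal per strain and treatment. The residual spread of each gene was shared over all strains and treatments, also for the difference in a single strain. Contrasts were the mean over strains of tolvaptan minus vehicle, the difference in each strain, a moderated F test of equal differences in all strains, and a moderated F test of equal vehicle means. All tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and genes were counted again at a fold of at least 1.5. The 38 gene lists were tested with camera at an inter-gene correlation of 0.01 and again with the correlation estimated for each list.

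Response size per strain was the mean log2 value of up to 50 genes that rose minus that of up to 50 that fell. These genes were called in the other 44 strains, and scan effects were first removed. Of these genes 33 to 50 rose and 16 to 43 fell. Each strain had an exact two-sided permutation test, whose smallest p with 4 against 4 animals is 0.0286.

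The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. For the averaged effect the rule took the 12 largest rises and 12 largest falls at adjusted p under 0.05 that had the same sign in scan 1 and in the later scans together. For each gene list that passed, it took up to 4 called members with the largest change, and 1 or 2 members for other lists. It took up to 12 interaction genes, 5 genes in each of the 3 strains with the most calls, and 10 genes for vehicle strain differences. Avpr1a, Avpr2, Cyp3a11, Cyp2b10, Abcb1a, Abcb11, Abcc2 and Slc10a1 were always named.

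A check of strain identity was added after seeing the data. Over the 500 probe sets that best separated the strains, each array was correlated with the median profile of the other arrays of its labelled strain. Treatment was not used. Arrays under 0.5 were called off their labelled strain. With 300 and 1000 probe sets the count was 34 and 35, against 34 with 500. No array was given another label. The limit of 0.5 was set after a stricter first rule, which also asked for a correlation with another strain higher by 0.2, had given 32 arrays. Also chosen after seeing the data were the counts without these arrays, without scan 2, without the 4 arrays of highest spread in relative log expression, without the strains concerned, the split of the response by scan, and the counts without single animals of 3 strains.

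The steps were tested on simulated arrays with the real spread and 14125 genes. For the averaged effect, changes of 1.1, 1.2, 1.5 and 2 fold were recovered in 56%, 94%, 100% and 100% of 50 genes each. For a single strain, changes of 1.5, 2 and 4 fold were recovered in 23.9%, 77.6% and 97.0% of genes. For the interaction, strain effects with an SD of 0.3, 0.6 and 1 on the log2 scale were recovered in 77.6%, 97.0% and 100% of genes. Among 13525 unchanged genes, 9 were called for the averaged effect, 17 for the interaction and 207 summed over the 45 strains, 9 of these in the strain that held the changes. For vehicle strain differences, 12 of 13925 unchanged genes were called. The simulated arrays vary independently between genes, which the real ones do not. They also have the same spread in every strain and treatment, and no array off its strain. With treatment permuted within strain and scan in the real arrays, the median was 1257 calls summed over strains. The simulated rates may therefore not hold for single strains.

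The alternatives covered scan date, filters, the choice of probe set, normalization, the variance prior, subsets of scans, an additive model, strains as the unit, and leaving out animals or strains. Strain variants under a probe can change its signal without a change in RNA.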

Results

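The data comprised liver expression profiles of 354 male mice of 45 Collaborative Cross strains, 175 given tolvaptan and 179 given vehicle, 24 h after treatment. The series concerns liver damage by tolvaptan, and the panel allows the response to be compared between genetic backgrounds. Over strain-informative probe sets, 34 arrays from 19 strains correlated at 0.32 or less with the other arrays of their labelled strain, while the other 320 correlated at 0.54 or more. Of the 34 arrays, 27 carried a vehicle label and 7 a tolvaptan label, and 22 lay in scan 2, 1 of 6 scan dates. Of the 34, 31 correlated at 0.76 or more with another strain. The labels were kept, and counts without these arrays are given beside the results.

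**Figure D1:**
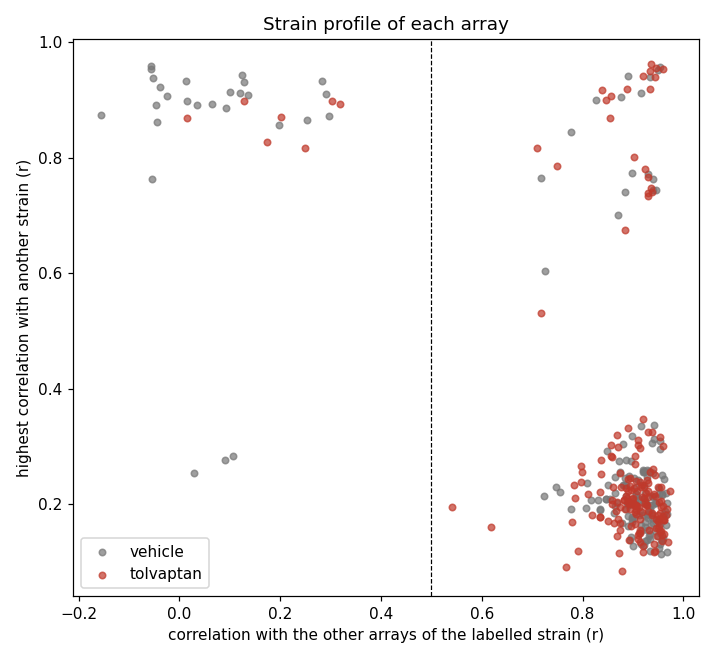
Correlation of each of the 354 arrays with the other arrays of its labelled strain (horizontal, r) against its highest correlation with another strain (vertical, r), with vehicle in grey and tolvaptan in red. The 34 arrays left of the dashed line at 0.5 do not match their labelled strain, and 31 of them match another strain at 0.76 or more.

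The first comparison asked which genes tolvaptan changed in the liver on average over the strains. The largest rises were in Derl3, a component of endoplasmic reticulum-associated degradation, and Saa3, an acute phase serum amyloid. Derl3 was 6.52 ± 1.44 (SD, n = 179) on the log2 scale under vehicle and 7.53 ± 1.69 (SD, n = 175) under tolvaptan. Its averaged change was 0.99 ± 0.13 (SE, adjusted p = 8.41e-09, limma), positive in 35 of 45 strains. Saa3 was 7.43 ± 1.19 (SD, n = 179) under vehicle and 8.33 ± 1.51 (SD, n = 175) under tolvaptan, a change of 0.91 ± 0.12 (SE), also positive in 35 strains. No other gene was called at a fold of at least 1.5.

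Smaller rises were measured in the protease inhibitor Slpi (0.47 ± 0.09, SE), in Wfdc12 (0.40 ± 0.09) and in Alas1, the rate-limiting enzyme of heme synthesis in liver (0.35 ± 0.07, 34 of 45 strains). The serine synthesis gene Psat1 was called at 0.32, with means of 2.47 and 2.79 that lie below the typical array median (2.89), near background, and 0.01 in scan 1. The transducin genes Gnat2 and Gnat1 rose by 0.27 and 0.26, and the transferrin receptor Tfrc by 0.25. Cela2a, Slc17a1 and the protein disulfide isomerase Pdia6 rose by 0.23, 0.22 and 0.20. Cela2a is an exocrine pancreas gene, and it was the only 1 of 12 tested pancreatic markers that was called. Of the 12, 5 had a positive change.

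Among genes that fell, N4bp2l1 fell by 0.27 and Adam11 fell by 0.24. Stab2, a scavenger receptor of sinusoidal endothelium, fell by 0.19, with a positive difference in only 12 of 45 strains. The glycine decarboxylase Gldc fell by 0.16, the sarcosine dehydrogenase Sardh fell by 0.15, and the urocanase Uroc1 fell by 0.15. Agbl3 fell by 0.16, with 3 of its 6 probe sets of the same sign. Ankrd24 fell by 0.15, with 1 of its 3 probe sets of the same sign. Fam220a, Coq10a, Rbm4 and Gm15417 fell by 0.15, 0.15, 0.14 and 0.13.

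Of 14125 genes, limma called 70, 46 higher and 24 lower, and 61 of them had the same sign in scan 1 and in the later scans. The same sign does not mean the same size: in scan 1 Sardh was -0.02, Uroc1 -0.01, Rbm4 -0.01, Coq10a -0.02, Ankrd24 -0.04 and Slc17a1 0.04, against -0.20, -0.19, -0.19, -0.19, -0.19 and 0.28 later. The count depended on which arrays entered. It was 44 without the 34 arrays off their strain, with 33 shared, and 300 in the 26 strains that have no such array, with 62 shared. Of the 24 genes named above, all kept their sign without the 34 arrays, but Wfdc12, Psat1, Gnat1, Tfrc, Cela2a, Slc17a1, Agbl3, Gldc, Ankrd24 and Coq10a were no longer called. Among called list members Pdia4 and Hp also lost their calls there. In the 26 strains 23 of the 24 were called, all but Agbl3. The SEs and calls above rest on the spread between animals within strains. With strains as the unit the count was 18. Among the 24 named genes plus Pdia4 and Hp, 18 lost their calls with strains as the unit. The count was 1 (Alas1) without scan 2, where 16 strains keep only 1 vehicle animal and 14 of them only 1 tolvaptan animal. Within single scans limma called 32 genes in scan 3 and 0 in scans 1, 2, 4 and 5, where 358, 865, 838 and 532 genes had an unadjusted p under 0.05.

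**Figure D2:**
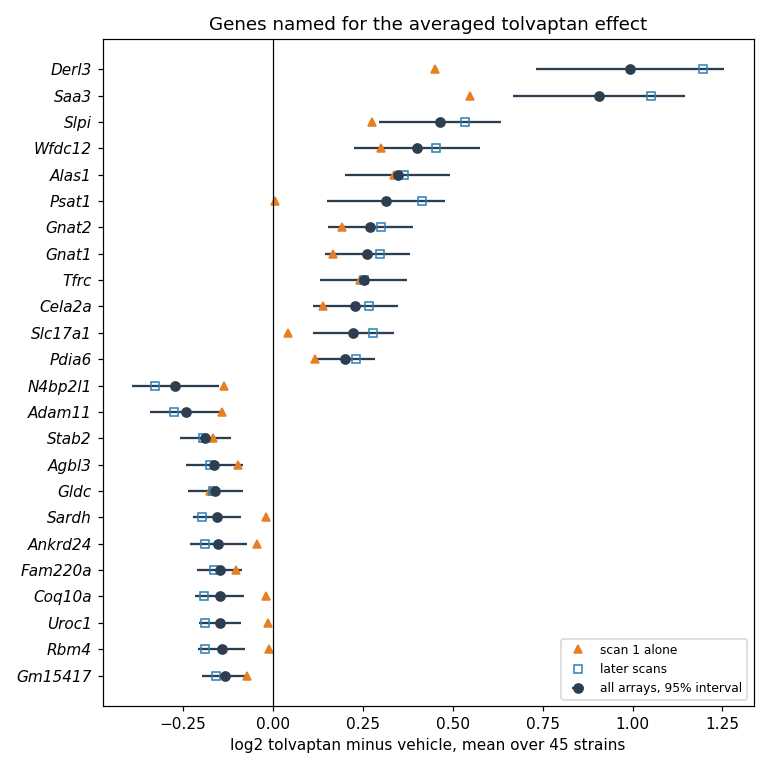
Change of each named gene as log2 tolvaptan minus vehicle averaged over 45 strains (horizontal), with 95% intervals for all arrays, and the change in scan 1 alone and in the later scans as points without error. Derl3 at 0.99 and Saa3 at 0.91 lie farthest from 0.

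Of the genes tied to the drug, Avpr1a, a vasopressin receptor, differed by -0.03 ± 0.07 (SE, adjusted p = 0.929), and Avpr2, the target, was too dim to be tested (mean 2.23). The drug-metabolizing Cyp3a11 differed by 0.10 ± 0.05 (adjusted p = 0.461) and the CAR target Cyp2b10 by 0.35 ± 0.17 (adjusted p = 0.470), with -0.09 in scan 1 and 0.47 later. The transporters Abcb1a (0.04, with -0.05 in scan 1 and 0.07 later), Abcb11 (-0.04), Abcc2 (0.14 ± 0.05, adjusted p = 0.143) and Slc10a1 (0.05) did not pass either. Abcb1a lay below the typical array median of 2.89 in both groups, with means of 2.57 and 2.61. In the 26 strains with no array off its strain, Abcc2 was called at 0.20 ± 0.05.

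Gene lists shifted by little. CAR and PXR targets, genes of xenobiotic metabolism, had a mean change of 0.08, with 1 of 25 members called over all genes (Alas1) and 4 adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). The acute phase list had a mean change of 0.10 (adjusted p = 0.194 with an estimated correlation). Saa3 and Hp (0.07) were called among its 30 members, and 9 higher and 1 lower adjusted over the list alone. For endoplasmic reticulum stress and the integrated stress response, 3 of 31 members were called higher, Psat1, Pdia6 and Pdia4 (0.20), and 7 adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). Pdia4 was -0.00118 in scan 1 alone and 0.27 in the later scans. NRF2 targets had a mean of 0.05 with 0 of 26 called and 4 adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). Cholesterol synthesis genes had a mean of 0.11 with 0 of 16 called and 3 adjusted over the list alone (adjusted p = 0.530 with an estimated correlation). In scan 2 alone their mean was -0.15, downward (adjusted p = 6.38e-05, camera at a correlation of 0.01). Proteasome subunits were higher in 27 of 28 members, by a mean of 0.03, with 0 called and 0 adjusted over the list alone (adjusted p = 0.261 with an estimated correlation). The heat shock list had a mean of 0.05 over 16 members, the immediate early list 0.07 over 17 and the ribosomal protein list 0.02 over 25, with 0 called in each. Adjusted over the list alone 3 immediate early genes passed. With an estimated correlation these lists had an adjusted p = 0.352, 0.530 and 0.194.

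Downward, urea cycle and amino acid catabolism genes had a mean change of -0.04, with Gldc and Uroc1 called among 29 and 3 adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). Periportal genes had a mean of -0.03 with Uroc1 called among 19 and 3 adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). The respiratory chain list had a mean of -0.02 over 64 members, with 0 called and 7 lower adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Stellate cell and fibroblast markers had a mean of -0.06, with 0 of 18 called and 2 adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). Male-biased genes also had a mean of -0.06, with 0 of 14 called and 0 adjusted over the list alone (adjusted p = 0.587 with an estimated correlation), and in scan 1 alone a mean of 0.11, upward (adjusted p = 0.0292, camera at a correlation of 0.01). Means also had the opposite sign in scan 1 alone for acute phase (-0.00300) and respiratory chain genes (0.00610), and in scan 2 alone for NRF2 targets (-0.04), periportal (0.03) and immediate early genes (-0.04), none of which passed there.

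By camera at a correlation of 0.01, 14 of 38 lists passed, 9 upward and 5 downward, against a median of 6 lists when treatment was permuted within strain and scan. With an estimated correlation camera passed 0, with 8 at an unadjusted p under 0.05. Markers of sinusoidal endothelium, Kupffer cells, neutrophils, T and NK cells, B cells, bile duct, red cells and fat did not pass at 0.01. Median, mean and test differed in sign in 6 lists, none of which passed: PPAR-alpha targets, gluconeogenesis, NF-kB genes, osmotic stress genes, erythroid markers and pancreatic markers.

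Lists that did not pass held 3 called members, Stab2, Cela2a and the bile acid enzyme Slc27a5, which fell by 0.05 and was named after its value was seen. Of their other members with the largest differences, Nqo1 had the lowest adjusted p, with 0.22 ± 0.06 (SE, adjusted p = 0.0534), and was called without the arrays off their strain (adjusted p = 0.0423). The fasting genes Ppp1r3c and Asns differed by -0.30 ± 0.09 and 0.24 ± 0.10, the fat synthesis genes Thrsp and Elovl3 by 0.23 and -0.18, and the clock genes Per3 and Wee1 by 0.23 and 0.22. Cyp4a10 and Cyp8b1 differed by -0.21 and -0.13, Cyp1a2 by -0.05, Cyp39a1 and Sult3a1 by 0.30 and 0.28, and Cyp2c37 and Lhpp by 0.21 and 0.12. Lcn2 and Cyp17a1 differed by 0.45 ± 0.20 and -0.24 ± 0.14, Slc38a2 and Aqp8 by 0.08 and -0.07, and Abcc4 by 0.10. The p53 targets Cdkn1a and Plk3 differed by -0.14 and 0.12, the cell cycle genes Ube2c and Kif20a by -0.18 and -0.09, Cxcl1 and Il18 by 0.20 and -0.11, and the interferon-responsive Usp18 and Psmb8 by 0.16 and 0.10. Among cell type markers, Cd68 and Cd74 differed by 0.14 and -0.09, S100a8 and S100a9 by 0.16 and 0.06, Ccl5 and Klrd1 by 0.09 and 0.06, and Cd79a and Cd37 by -0.07 and 0.06. Ehd3 differed by -0.09, Krt19 and Pkhd1 by -0.13 and -0.10, Alas2 and Car1 by -0.10 and -0.07, Try5 by -0.11, and Car3 and Fabp4 by -0.27 and 0.11. Kif20a, Klrd1, Krt19, Pkhd1 and Try5 lay below the typical array median in both groups. In scan 1 alone Lcn2, Cyp39a1 and Asns had the opposite sign, at -0.28, -0.20 and -0.06, as did Cyp1a2, Elovl3, Il18, Aqp8, Cd74, Alas2, Car1 and Fabp4.

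**Figure D3:**
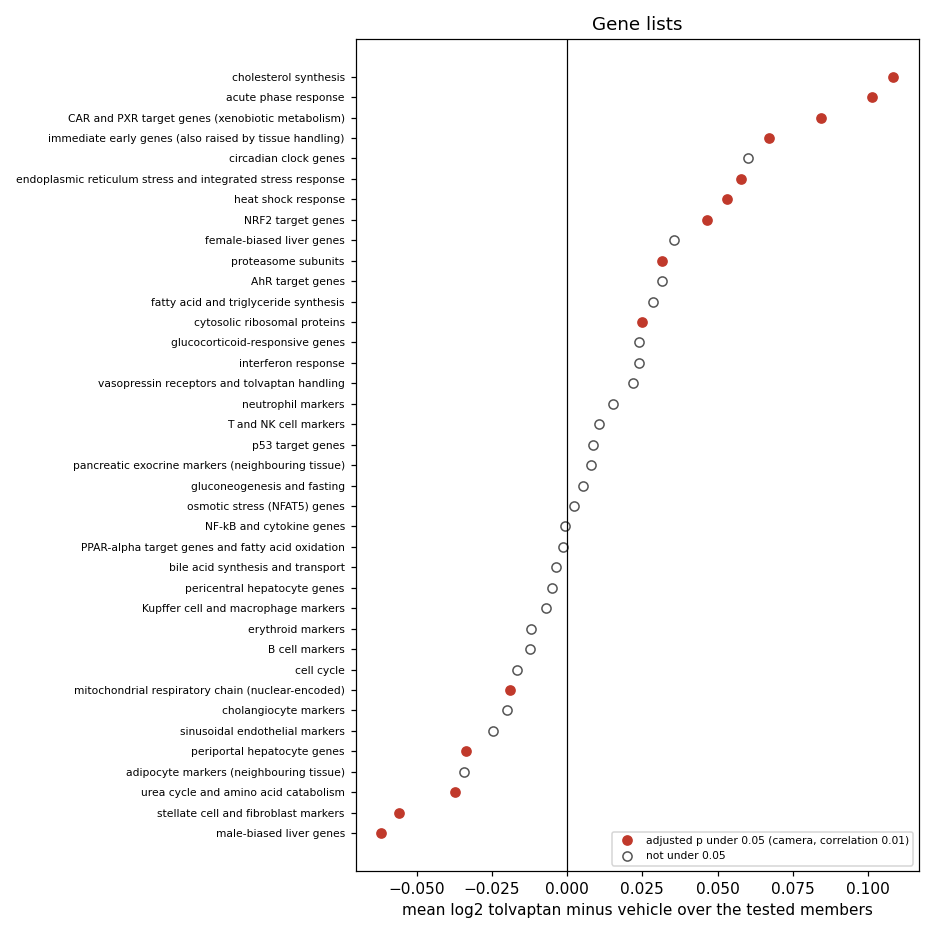
Mean log2 tolvaptan minus vehicle over the tested members of each of the 38 lists (horizontal), filled red where camera at a correlation of 0.01 gave an adjusted p under 0.05. The means run from -0.06 to 0.11, and 14 lists are filled.

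The second comparison asked whether the response depended on the strain. The interaction test called 3 genes, and 20 of 100 splits by treatment within strain and scan, the real one included, called as many. Stab2 ranged from 0.89 ± 0.24 (SE) in OR13421 to -1.23 ± 0.24 in OR5119 (adjusted p = 0.00212). Cd74, the invariant chain of MHC class II, ranged from 1.19 ± 0.36 in OR13421 to -1.67 ± 0.37 in OR5119 (adjusted p = 0.0275). Gm20319 ranged from 2.64 ± 0.39 in AU8024 to -1.74 ± 0.39 in AU8021 (adjusted p = 0.00964). OR13421, OR5119, AU8024 and AU8021 each hold arrays off their strain. The count was 26 without those arrays, where 2 of these 3 genes stayed called. It was 3 in the 26 strains that have none, where Stab2, Cd74 and Gm20319 were no longer called. That setting leaves out the strains with their highest and lowest differences, so the loss of these calls decides little.

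Within single strains, limma called the most genes in AU8049 (763), IL16750 (365) and OR5119 (269), of 1785 calls summed over strains, a sum that 19 of 100 such splits reached, the real one included. Without the arrays off their strain the order was AU8049 (1032), AU8033 (501, against 13 with all arrays), OR5119 (292), and IL16750 had 39. AU8033 then kept only 2 vehicle and 3 tolvaptan animals. With all arrays limma called 0 in 19 of 45 strains, where 180 to 1090 genes had an unadjusted p under 0.05. In AU8049 the largest changes were in the pyruvate dehydrogenase kinase Pdk4 (3.60 ± 0.96, SE), Gadd45b (3.50 ± 0.78), Hilpda (2.87 ± 0.39), Sox9 (2.66 ± 0.39) and Htra1 (2.45 ± 0.35). These SEs use a spread shared over all strains. Over the 4 tolvaptan animals of this strain the SDs were 3.47, 3.94, 3.16, 2.88 and 2.83, in the same order. Sox9 was 2.76 ± 0.19 (SD, 4 animals) under vehicle, below the typical array median of 2.89, and 5.43 ± 2.88 (SD, 4 animals) under tolvaptan, with single values of 8.33, 7.47, 2.79 and 3.12 in tolvaptan animals 345 to 348. In the same 4 animals Hilpda was 10.46, 9.67, 4.86 and 4.40, Gadd45b 11.90, 11.47, 4.60 and 5.16, Pdk4 12.06, 11.62, 6.39 and 5.36, and Htra1 7.90, 8.05, 2.86 and 3.30. Without animal 345 the change was 2.32 for Gadd45b, 1.86 for Hilpda and 1.71 for Sox9, and without 346 it was 1.61 for Htra1. Gadd45b and Pdk4 were not called without 345 or without 346, nor Pdk4 without vehicle animal 341. Called genes in this strain numbered 23 without tolvaptan animal 345, 45 without 346, 1545 without 347, 1652 without 348 and 484 without vehicle animal 342.

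In IL16750, Gm26910 (-3.45), Plpbp (-3.36), Ces2b, Slc34a2 (2.97) and Gdpd3 (2.94) had the largest fitted changes. Over the 4 vehicle animals the SDs were 2.85, 3.99, 4.55, 2.88 and 2.86, in the same order. The tolvaptan means of Gm26910 (2.55) and Plpbp (1.71) lie below the typical array median of 2.89, near background, so the size of these changes is uncertain. Called genes numbered 6 and 1107 without vehicle animals 124 and 121, both off their strain, and 791 and 967 without vehicle animals 122 and 123. Without the 4 arrays of highest spread in relative log expression this strain had 8 called genes. Among single animals left out, only 124, off its strain, gave a count this low. Array quality therefore cannot be told apart from the strain mismatch here. Without tolvaptan animals 127 and 128 the count was 199 and 121. None of the 5 genes was called without animal 124, where Plpbp was -2.10, Ces2b 1.79 and Slc34a2 1.85, and without 121 Ces2b was 1.67 and not called. Plpbp alone stayed called without each of the 7 animals other than 124. Without the 34 arrays off their strain the difference was 0.08 for Plpbp and -0.89 for Ces2b.

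In OR5119, Psat1 was called at 3.50 ± 0.56 (SE, from the shared spread). Its vehicle mean was 2.33 ± 0.42 and its tolvaptan mean 5.77 ± 2.38 (SD, 4 animals each). The vehicle mean lies near background, so the size is uncertain. The acute phase gene Orm2 rose by 3.33, Derl3 by 3.29 and Saa3 by 3.08, while the MHC class II gene H2-Ab1 fell by 2.91. Called genes numbered 165 without vehicle animal 364, which is off its strain, and 432, 591, 126 and 95 without tolvaptan animals 365, 366, 367 and 368. Psat1 stayed called without each of the 8 animals. Orm2 lost its call without 361, 363, 364, 365, 367 or 368, Derl3 without 363, 364, 365 or 367, Saa3 without 362, 363 or 365, and H2-Ab1 without 364, 367 or 368. Fitting each strain on its own arrays gave 41 calls in all, and the 15 genes named in these 3 strains, Psat1 included, all lost their calls.

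The response score, built from genes called in the other strains, was higher under tolvaptan in 36 of 45 strains, with a mean of 0.26 ± 0.34 (SD over strains) on the log2 scale. It was largest in AU8033 (1.09), OR5119 (0.91) and OR5035 (0.87), and lowest in OR13421 (-0.63) and OR477 (-0.54). The score rests on 49 to 93 genes that differ between strains, so its sizes are not strictly comparable. AU8033, OR13421, OR5119 and OR477 hold 3, 2, 1 and 1 arrays off their strain. Without such arrays the score, over other genes, was 2.06, -0.81, 1.40 and -0.69 in these strains and 1.30 in OR5035, and AU8024 was lowest at -0.83. AU8033 and AU8024 then held 2 vehicle and 3 tolvaptan animals each (exact permutation p = 0.1 and 0.3). With the 10 permutations there, 0.1 is the smallest p this test can give. In AU8033 the score rested on 6 genes that rose and 11 that fell. With all arrays, 15 strains had p under 0.05 by exact permutation, 14 higher and 1 lower (OR13421). After adjustment 0 did, with a lowest adjusted p of 0.0857. No strain could pass this adjustment by itself, since many strains would have to reach the smallest possible p together. The adjusted result therefore does not show that single strains did not respond. The score averaged 0.04 ± 0.43 (SD) in the 16 strains with arrays in scan 2 and 0.38 ± 0.21 in the other 29 (permutation p = 0.00112, adjusted p = 0.00362 over 5 comparisons by scan). The score was higher in 35 of 45 strains (mean 0.34) without the arrays off their strain, in 28 of 29 (mean 0.40) without the strains that have arrays in scan 2, and in 26 of 26 (mean 0.44) without the strains that have an array off its strain. The split by scan and these exclusions were chosen after the data were seen. Without scan 2, where the score rests on 1 to 7 genes, it was higher in 15 of 36 strains with a score, 14 of which keep 1 animal in a treatment, and the mean over strains was -0.15.

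**Figure D4:**
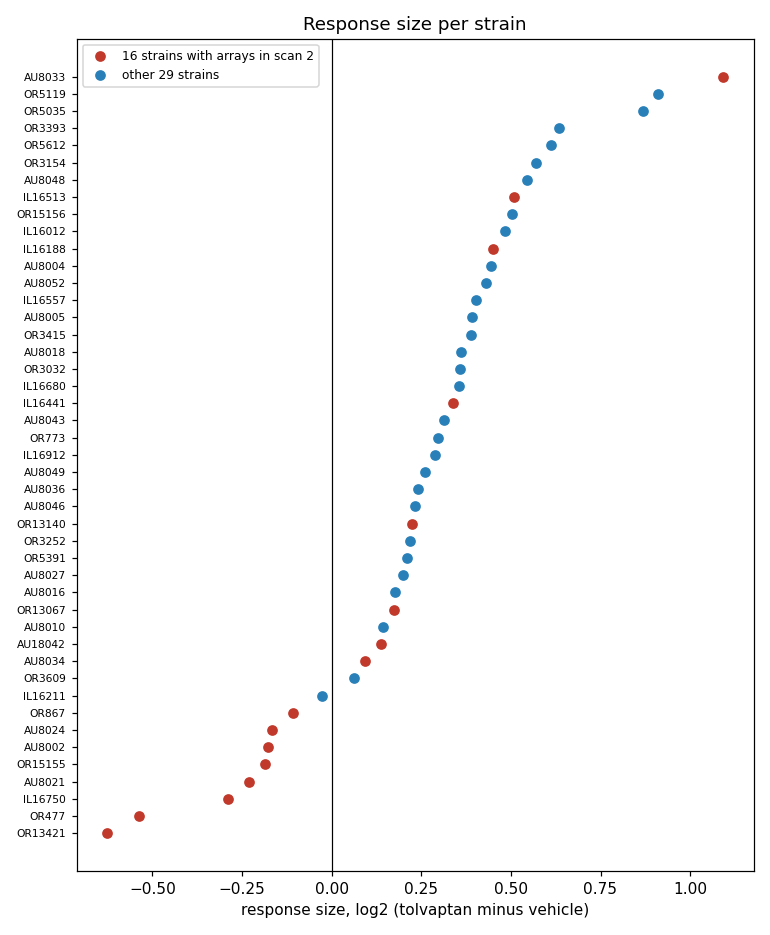
Response size of each strain (horizontal, log2 tolvaptan minus vehicle), with the 16 strains that have arrays in scan 2 in red and the other 29 in blue. The lowest strain is OR13421 at -0.63 and the highest is AU8033 at 1.09.

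The third comparison described baseline differences between strains. Vehicle livers differed between strains in 10580 of 14125 genes, and the median share of variance between strains was 17.0% (quartiles 7.47% and 29.3%). The largest SDs over strain means were 3.11 in the glycosyltransferase Ugt3a2 and 3.04 in Obp2a. Ugt3a2 ranged from 11.62 in AU18042 to 3.50 in OR15156, and Obp2a from 11.49 in AU8036 to 1.52 in OR867. H2-Bl, Gm4788, the sulfotransferase Sult3a1 and the carboxylesterase Ces2b had SDs over strain means of 2.58, 2.49, 2.36 and 2.28. Nlrp12, Cyp2b10, Akr1c18 and Fam107a had SDs of 2.26, 2.24, 2.24 and 2.19. Cyp2b10 ranged from 11.64 in IL16513 to 2.47 in OR5035. The low ends of all of these genes but Ugt3a2 lie below the typical array median of 2.89, near background, so the size of their ranges and SDs is uncertain. The count was 10391 without the 34 arrays off their strain. The share of variance used all 179 vehicle arrays, centred within each scan, and was not computed without the 27 vehicle arrays off their strain. Later scans mostly hold different strains, so this centring can remove part of the difference between strains. Strain variants under a probe can give such differences on an array.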

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

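Tests chosen only after the result was seen were the 3 of the arrays off their strain, the 3 of AU8049 and the comparison of scan 1 with later scans in the 29 other strains. The comparison of the 16 strains with arrays in scan 2 with those 29 was also chosen after the data were seen. The splits and the tests giving -0.355 and -0.460 were written before their values were seen. The tolvaptan effect differed between strains for 3 genes, Gm20319 (F = 2.61), Cd74 (F = 2.46) and Stab2 (F = 2.83). Chance cannot be excluded for this count: of 100 splits, the real one and permutations of treatment within strain and scan, 20 gave as many genes, the real one included, and the highest other split gave 16, several times the real count, which points to a structure of the samples that was not tested further. It cannot be excluded for the 1785 calls summed over strains either, with 19 of 100 splits as large, the real one included, and a highest other of 3160. Chance can be excluded for the count of 70 averaged genes (only the real one of 100 splits, highest other 1). The same holds for the count of 10580 genes that differed between vehicle strains (only the real one of 100, highest other 2887). There strain labels were permuted within scan. Both tests concern the counts and do not exclude chance for any single gene. For the 14 gene lists at a correlation of 0.01, 3 of 100 splits, the real one included, passed as many. That share is under 0.05, but the highest other split passed 15, the median of the others was 6, and 0 lists passed with an estimated correlation, so chance is not excluded for any single list.

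Of the 354 arrays, 34 do not match their labelled strain. Low array quality is argued against by a median correlation of 0.893 with the best other strain, while the 0 of 34 arrays whose best strain is a close relative decide nothing on related strains, since an array of a relative would also match its own strain and was thus not selected. In scan 2, 11 of the 22 such arrays matched the strain 1 or 2 plate positions before their own, against at most 6 in 10000 permutations (p = 1e-04, the smallest they can give). Labels displaced along the plate are therefore a candidate explanation for part of scan 2, where the other 11 arrays stay open. So do the 12 arrays in other scans, and no biological explanation was tested. Of the 34 arrays, 13 best matched a strain that itself holds an array best matching their labelled strain. The 3 arrays that correlated under 0.5 with every other strain were OR13067 vehicle animals 101 and 102 and AU18042 vehicle animal 94. They correlated at 0.87 to 0.94 with one another.

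The response was smaller in the 16 strains with arrays in scan 2. If treatment labels were displaced in scan 2 alone, the response of these strains would be higher in their scan 1 arrays, but it was lower there, by -0.355 (permutation p = 0.015), and in the other 29 strains scan 1 was also lower than the later scans, by -0.183 (permutation p = 0.00969). This argues against displacement in scan 2 alone as the whole cause, although a count of strains without scan 2 had been seen before the test was written. Within scan 1 the 16 strains lay -0.460 below the others (permutation p = 0.00145), as strains that respond less would. Their scan 1 responses had an SD of 0.689 against 0.251, and each compares 1 tolvaptan animal with 1 vehicle animal. Scan 1 also holds 6 arrays off their strain, 5 of them vehicle, among them IL16750 animal 124 and AU18042 animal 94 of these strains. The test was not rerun without them, so it does not tell strains that respond less from label errors. Labels displaced in scan 1 as well stay open, as untested.

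In AU8049, 763 genes were called, and the count was 23 and 45 without tolvaptan animals 345 and 346, and 1545 and 1652 without 347 and 348. Low array quality is argued against by a highest interquartile range of relative log expression of 0.472 over the strain's 8 arrays, under the limit of 0.573, and another strain by a lowest correlation of 0.768 with the strain's own profile. More bile duct cells cannot be told apart from other causes of the rise in Sox9: the 10 other bile duct markers had a median change of -0.0941, but only 4 of them lie above the array median. A response of this strain to tolvaptan, or an event in single animals, stays open as untested.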

How the results depend on the processing

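All settings that leave out arrays off their strain, scan 2, high-spread arrays or the strains concerned were chosen after seeing the data. The averaged count of 70 genes lay between 57 and 101 without scan date in the model, with other filters, probe set rules, normalization and priors, and in the additive model. It was 18 with strains as the unit, 0 in the earliest scan, 158 in the later scans, 0, 32, 0 and 0 in scans 2, 3, 4 and 5 alone, 44 without the arrays off their strain, 1 without scan 2, 7 without both, 233 without the strains that have arrays in scan 2 and 300 without the strains that have an array off their strain. The interaction count of 3 was 5 with the filter on the mean over all arrays, 11 in the later scans, 7 without the high-spread arrays, 26 without the arrays off their strain, 455 without scan 2 and 38 without both. The 1785 calls summed over strains were 41 with each strain on its own arrays, 7591 without scan 2 (4251 of them in IL16750, where the only vehicle animal left is off its strain), 3081 without both and 1106 without the strains that have an array off their strain. Lists that pass, 14 in all arrays, were 0 with an estimated correlation, 6 in scan 2 alone, 3 in scan 5 alone, 5 without scan 2 and 6 without both. The response was higher in 15 of 36 strains with a score without scan 2, with a mean of -0.155, rather than in 36 of 45 with a mean of 0.257, and the score then rests on 1 to 7 genes. It was higher in 35 of 45 (mean 0.338) without the arrays off their strain, in 29 of 40 (0.199) without both, in 28 of 29 (0.398) without the strains that have arrays in scan 2 and in 26 of 26 (0.436) without the strains that have an array off their strain. Without the high-spread arrays IL16750 had 8 calls, against 365 with all arrays. Settings with fewer arrays test less, and without scan 2 lone animals are assumed to vary like the others. The causes were otherwise not tested.

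Leaving out the animals of each place in the numbering in turn gave 3 to 162 averaged genes, 1 to 21 interaction genes, 882 to 3314 calls summed over strains, 11 to 13 lists, 33 to 40 strains with a higher response and 8423 to 9629 vehicle genes. Leaving out each strain in turn was run for 3 of these, and gave 49 to 121 averaged genes, 1 to 8 interaction genes and 12 to 15 lists. The vehicle count stayed within 1.5 times of 10580 in the settings run.

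In the earliest scan the change of Pdia4 was -0.00118, and list means that turned were acute phase -0.00300, glucocorticoid -0.0990 (adjusted p = 0.00904), male-biased 0.113 (adjusted p = 0.0292) and respiratory chain 0.00610. In scan 2 alone Stab2 was 0.00156, PPAR-alpha 0.0573 (adjusted p = 0.0483), NRF2 -0.0450, cholesterol -0.151 (adjusted p = 6.38e-05), periportal 0.0326 and immediate early -0.0362. In scan 4 alone PPAR-alpha was 0.10 (adjusted p = 0.00820), respiratory chain 0.000495 and neutrophil -0.118 (adjusted p = 0.0354). With these animals left out in turn the glucocorticoid mean ran from -0.0478 (adjusted p = 0.0250) to 0.0546. Without the arrays off their strain Plpbp was 0.0762 and Ces2b -0.889 in IL16750. Without scan 2 and those arrays the male-biased mean was 0.0238. The direction by camera, which is relative to all genes, turned while the mean kept its sign for ribosomal proteins in the earliest scan (0.00686), CAR and PXR targets in scan 2 (0.0163), acute phase (0.0141) and male-biased genes (-0.0176) in scan 4, proteasome subunits in scan 5 (0.00462) and the respiratory chain without scan 2 and the arrays off their strain (-0.000617). The cause was not tested. Scan 6 alone was not run, since it holds 1 strain with both treatments. Animal numbers are not shared between the groups and pair no arrays, while strains do pair the groups, and the fit with strains as the unit gave the 18 genes. Dim genes such as Avpr2 lie near background and limit what the arrays can show.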

Other observations

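The subsets, genes and markers below were chosen after the data were seen, and the 38 lists before.

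In AU8049, tolvaptan minus vehicle over 4 animals each, immediate early genes had a median difference of 1.05, with 16 of 17 higher, and glucocorticoid-responsive genes 0.57, with 15 of 17 higher. Kupffer cell and macrophage markers had a median of -0.40, with 1 of 18 higher, PPAR-alpha targets -0.34, with 5 of 30 higher, pericentral genes -0.31, with 7 of 22 higher, and interferon genes -0.31, with 5 of 27 higher. AhR targets had a median of 0.29, with 7 of 7 higher, and clock genes 0.29, with 12 of 17 higher. These medians were not tested, and the calls rest on single animals.

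In the 26 strains with no array off its strain, cholesterol synthesis genes had a mean change of 0.22. Sqle, Msmo1 and Insig1 were called at 0.58 ± 0.15, 0.56 ± 0.13 and 0.45 ± 0.10 (SE), and Nqo1, an NRF2 target, at 0.37 ± 0.07. The hepcidin gene Hamp2 and the transporter Slc22a7 were called at -0.58 ± 0.14 and -0.43 ± 0.10. By camera at a correlation of 0.01, 19 lists passed in these strains. Of these, 6 did not pass in all arrays: sinusoidal endothelial markers (mean -0.05) and Kupffer cell and macrophage markers (mean -0.05), and upward AhR targets, fatty acid synthesis, vasopressin and tolvaptan handling, and clock genes. Male-biased genes no longer passed. With an estimated correlation 1 list passed, CAR and PXR targets (mean 0.13, adjusted p = 0.0399), while the endothelial and Kupffer cell lists had an adjusted p = 0.334 and 0.665.

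Xist, the RNA of the inactive X chromosome, was 11.09 in OR3415 vehicle animal 481 and at most 3.62 in every other array, although all animals are labelled male. In the same array the Y-linked Eif2s3y was 5.33, Kdm5d 4.82 and Uty 4.50, against medians of 6.48, 4.69 and 4.06 in the other arrays of the strain. The strain profiles of AU18042 and AU8021 correlated at 0.98, those of AU8024 and AU8033 at 0.93, and those of IL16012 and IL16912 at 0.79, against at most 0.41 for any other pair.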
